A study of Homo sapiens with 8 samples.

How the data were processed

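H3K4me1 ChIP-seq was done in MDA-MB-231 cells of 2 genotypes, control and ARID1A knockout, with 2 immunoprecipitated and 2 input samples per genotype. Groups were taken from the genotype and antibody labels. Per the labels' protocols, chromatin was digested with micrococcal nuclease before immunoprecipitation. The protocol text names the antibody as one against H3K4me3, whereas the antibody label and the sample titles say H3K4me1, and H3K4me1 is used throughout. The protocol also mentions a control IgG, which was not analysed here.

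Per the submitters' processing notes, Bowtie2 2.3.5.1 and MACS2 2.2.6 were used with hg38. Settings, thresholds and the handling of duplicate reads are not given in the sources used here. The authors deposited 1 peak list per genotype, immunoprecipitate over input. How the 2 replicates entered each call is not given in the sources used here, and the lists were treated as pooled. Per the file headers, the deposited lists give for each peak its position, the pileup (a signal of stacked fragments), the fold enrichment, and the −log10 of a p and a q value. The columns include no summit. The authors' fold and −log10 q are values of a peak against its own input and were used only to rank and filter peaks within a list. The lowest deposited −log10 q was 1.01 in each list. No read count was used, so depth is unknown, and a peak near the threshold is less certain than a strong one.

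The shortest peak was 312 bases in the control list and 361 in the knockout list, and the smallest gap between neighbouring peaks was 1249 and 1445 bases, in each list 4 times the shortest peak plus 1. From this the lists appear to have been called with different fragment lengths, a setting that no source used here states. It changes which peaks merge and how wide they are, and median widths were 1386 and 1587 bases. An alternative chosen after this was seen applied the same merging distance (1444 bases) and the same shortest peak (361 bases) to both lists. It does not redo the pileup or the q values. Median pileup was 13.6 in the control list and 16.4 in the knockout list. With different fragment lengths, the same cutoff of −log10 q or fold need not be equally strict in both lists.

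Peaks on chromosomes 1 to 22 and X were used, leaving out 6 control and 3 knockout peaks on other sequences. A peak counted as shared when it overlapped a peak of the other list by at least 1 base. Chance overlap was measured with 100 random shifts of the other list around each chromosome. Percentages have 95% exact (Clopper-Pearson) binomial intervals. These intervals cover counting error over peaks only, not the spread between cultures, and neighbouring peaks are not independent. No p-value was computed, because each genotype had a single list.

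Gene positions and symbols came from the RefSeq gene table of GRCh38.p14, whose chromosome coordinates are those of hg38. All 517 entries of the 25 gene lists matched a protein-coding symbol, 2 of them through an older symbol. The table used gives neither strand nor exons. The planned windows of 50000 and 10000 bases around transcription start sites and the classes of UTR, exon and intron were therefore not run, and the planned motif counts were not run because no genome sequence was used. In their place, covered bases were counted over the gene record with 5000 bases on either side, which had been listed as an alternative before the data were examined. Each peak midpoint was classed as within 1000 bases of either end of a protein-coding record, inside a record, within 50000 bases of one, or farther. Windows with 10000 and 50000 bases on either side of the gene were added after the data were seen.

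A gene was called higher or lower when the lists differed by at least 1000 covered bases. For each gene list the median difference was ranked among 10000 random lists of the same size matched on deciles of mean coverage, which describes these 2 lists and is not a test across replicates. Genes were named by a rule fixed before the data were examined, applied to the window just described. It took the 10 largest positive and the 10 largest negative differences in covered bases, skipping a gene whose window overlapped one already taken. It also took the 10 single-list peaks of highest −log10 q in each list with the nearest protein-coding gene, ARID1A, and up to 2 members of each gene list in each direction with at least 1000 bases of difference. Some single-list peaks and list members were left out for length, and 1 gene that the rule named is not reported here. Genes named for regions of 5 Mb were chosen after the data were seen.

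The local input background behind each peak was estimated as (pileup + 1) / fold − 1, assuming the pseudocount of 1 that MACS2 uses by default. The authors' values are averages over a peak, so the estimate is approximate. Its lowest value was 2.40 in the control list and 2.60 in the knockout list. The median over the peaks of a chromosome or of a region of 5 Mb was divided between genotypes. Chromosome ratios were then divided by the median ratio over chromosomes, 1.22, and region ratios by the median ratio over regions, as a rough measure of relative copy number. Where the control median was within 3% of its lowest value, in 25 of 571 regions and on chromosome X, a higher ratio cannot be ruled out. In 11 of these regions the knockout median was within 3% of its lowest value as well. There the ratio was held near that of the 2 lowest values (about 0.89) and says nothing in either direction.

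Alternatives planned before the data were examined were a −log10 q of at least 5, a fold of at least 4, all sequences, merging of peaks within 1000 bases, other overlap rules, lists of equal length, quartiles of fold, other location windows, and a log2 ratio of covered bases. Overlap, coverage and list ranking were tested on simulated data first. All 200 removed and all 200 added peaks were recovered among 82994 peaks, and 200 of 200 gene windows equalled a direct sum. Of 20 simulated lists of 20 genes out of 19974, 8 fell below the central 95% of random lists after 1000 bases were removed per gene, 20 after 2000 bases, and 0 with none removed. For lists, only equal losses in every member and the lower end of the ranking were simulated. Lists above the central 95%, and changes in only some members, were not. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.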

Results

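Monomethylation of lysine 4 on histone H3 (H3K4me1), a chromatin mark found at enhancers and around active genes, was profiled by chromatin immunoprecipitation and sequencing in MDA-MB-231 cells, an established line of triple-negative breast cancer. Control cells were compared with cells in which ARID1A had been knocked out. ARID1A encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The 8 samples formed 4 groups of 2, an immunoprecipitated group and an input group for each genotype. The deposited results were 1 list of H3K4me1 peaks per genotype, immunoprecipitate over input, in hg38 coordinates. The control list held 83000 peaks, of which 82994 lay on chromosomes 1 to 22 and X, and the knockout list held 73603, of which 73600 lay there. Read totals per sample were not used here, so the sequencing depth behind a peak is unknown. With 1 list per genotype there was no spread between replicates to set a difference against, and each difference given here describes these 2 lists with no test across replicates.

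The comparison of the genotypes asked where H3K4me1 peaks differed between ARID1A knockout and control cells. At ARID1A itself (chromosome 1, 26696015 to 26782104, counted with 5000 bases on either side), 8 control peaks covered 44673 bases and 9 knockout peaks covered 39191 bases. A peak list of a histone mark does not show whether the gene product was lost, so the locus does not check the knockout label.

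The gene with the largest excess of covered bases in the knockout list was FMN2, a formin that nucleates actin filaments (chromosome 1, 240091883 to 240475187), with 40523 bases in the control list and 114890 in the knockout list. TCF4, a basic helix-loop-helix transcription factor gene (chromosome 18, 55222185 to 55635957), carried a single control peak covering 361 bases, against 24 knockout peaks covering 64410 bases. Coverage was also higher in the knockout list at KYNU, which encodes kynureninase of tryptophan breakdown (10334 to 56987 bases), and at TIAM1, which encodes an exchange factor for the GTPase Rac (29386 to 75351 bases). In the other direction, LIMCH1, an actomyosin regulator gene (chromosome 4, 41359607 to 41700044), had 147284 covered bases in the control list and 64102 in the knockout list. DLC1, which encodes a GTPase-activating protein (chromosome 8, 13083361 to 13604620), had 159399 and 78181.

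Next among the 10 genes with the largest excess in the knockout list, ARHGAP24 and ARHGAP42, which encode GTPase-activating proteins, had 50245 and 43614 covered bases in the control list and 112561 and 105028 in the knockout list. The receptor phosphatase gene PTPRG had 89552 control and 145462 knockout bases, and the formin gene FMN1 had 49894 and 93634. EDIL3, which encodes a secreted integrin-binding protein, had 42755 and 85611 bases, and the glypican gene GPC6 had 74334 and 115966. Among the 10 genes with the largest deficit, SIPA1L3 had 102780 control and 40368 knockout bases and the adaptor gene BCAR3 had 169190 and 113524. LPP, which encodes a LIM-domain protein of cell adhesions, had 186969 and 136702 bases. ANKRD11, a chromatin regulator gene, had 140536 and 94169 bases, and PALM2AKAP2 had 155384 and 114794. ZFAND3 had 80429 and 40555 bases, and MACF1, which encodes a linker of microtubules and actin, had 149224 and 111697. At FMN2 and GPC6 the input background implied by the lists was 1.44 and 1.48 times the genome-wide ratio of knockout to control, and at LPP it was 0.629 times that ratio. For the other 16 of these 19 genes it lay between 0.851 and 1.07. At TCF4 (0.919) a higher ratio cannot be ruled out, because the control background was near the lowest of its list.

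**Figure D1:**
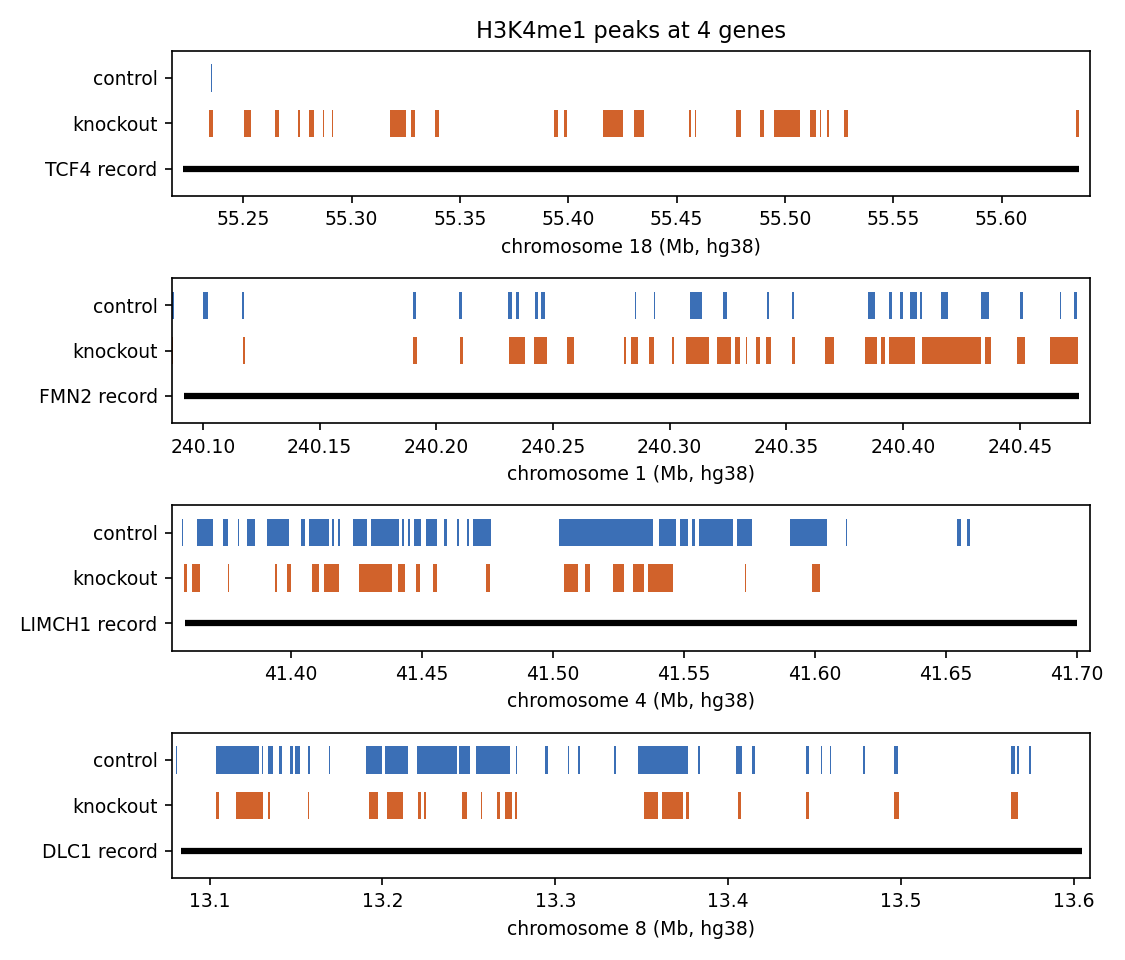
Each panel maps H3K4me1 peaks (boxes) of the control list (blue) and the ARID1A knockout list (orange) along 1 gene, with position in Mb of hg38 on the horizontal axis and the gene record as a black bar. TCF4 holds 1 control and 24 knockout peaks and FMN2 25 and 26, while LIMCH1 holds 31 and 19 and DLC1 32 and 20.

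Over all 19974 protein-coding genes, coverage was at least 1000 bases higher in the knockout list at 4033 genes and at least 1000 bases lower at 5994, and it differed by less than that at 9947. No peak of either list lay at 3160 genes, peaks of the control list alone lay at 870, and peaks of the knockout list alone lay at 451. The ranking by bases favours long genes. Among peaks with a −log10 q of at least 5, the direction was opposite at KYNU, with 4836 control and 4746 knockout bases. TCF4 then kept 0 control and 3272 knockout bases, and FMN2 0 and 70893. Differences shrank by more than 1.5 times at TIAM1 (6013 control and 15167 knockout bases), ANKRD11 (79136 and 70408) and ZFAND3 (32027 and 23194), and likewise at PTPRG, LIMCH1, DLC1, SIPA1L3 and PALM2AKAP2.

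The strongest peaks that had no counterpart in the other list were each assigned to the nearest protein-coding gene. In the control list these lay at SLC43A1, an amino acid transporter gene (chromosome 11, 57493715 to 57494954, −log10 q 16.6), ZNF503 (chromosome 10, 75357607 to 75360853, 15.6), INKA2 (chromosome 1, 111733199 to 111734584, 14.8) and TNS1, which encodes the focal adhesion protein tensin (chromosome 2, 217917777 to 217924183, 14.8), each overlapping the gene record. Of the next 4, those at MMP24, SLC13A3 and APBA1 overlapped the gene record and 1 lay 1580 bases from SYNGR4. In the knockout list the first overlapped AFAP1L2 (chromosome 10, 114374943 to 114376889, −log10 q 17.5) and the second 631 bases from GDNF, which encodes a neurotrophic factor (chromosome 5, 37810157 to 37812046, 17.3). The third lay 55471 bases from THY1, a cell surface glycoprotein gene (chromosome 11, 119480456 to 119481329, 15.7), and the fourth 44687 bases from the collagen gene COL6A1 (chromosome 21, 46049735 to 46050809, 15.6). ADAMTS15, RAD51B, ZHX2 and TMEM131 came next. The peaks at ADAMTS15, RAD51B and TMEM131 overlapped the gene record, whereas that assigned to ZHX2 lay 85205 bases away from it. These −log10 q values are the authors' own and rank peaks within a list. The nearest peak of the opposite list was 1688 bases away at GDNF and 38649 bases away at ZNF503.

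Genes were then grouped by 25 lists chosen before the data were examined. Lipid and cholesterol synthesis genes had more covered bases in the knockout list, with 12 of 18 genes at least 1000 bases higher and 4 at least 1000 bases lower. MVD, an enzyme gene of the mevalonate pathway, had 4565 control and 14704 knockout bases, and SCD, the stearoyl-CoA desaturase gene, had 7950 and 16206. ACACA, whose product makes malonyl-CoA, went the other way with 35602 and 29751 bases, as did the regulator SREBF1 with 19575 and 16882. The median difference was 2418 bases, at percentile 99.95 of 10000 random lists of the same size matched on covered bases.

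TGF-beta pathway genes also had more covered bases in the knockout list, with 14 of 22 genes higher and 6 lower. The receptor genes TGFBR3 and TGFBR2 had 54782 and 51315 control bases and 87164 and 66973 knockout bases. SKI, a repressor of the pathway, had 44597 control and 26087 knockout bases, and the signal transducer SMAD2 had 16211 and 7934. The median difference was 1928.5 bases, at percentile 99.89. Among peaks with a −log10 q of at least 5 the percentile was 91.3, inside the central 95% of random lists. The other 23 lists lay inside that central range at the authors' threshold, and 1.25 of 25 lists would be expected outside it by chance.

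YAP-TEAD target genes were mostly less covered in the knockout list, with 14 of 24 genes lower and 5 higher. Their median difference was -1286 bases, at percentile 24.1 of matched random lists, whose own median was -615.5 bases. At a −log10 q of at least 5 the median turned to 172 bases (percentile 45.0). The largest deficits of this list were DLC1, named above, and CRIM1, with 149984 control and 117872 knockout bases, and its largest excess was PTPN14, with 112824 and 125254, in a region with an implied background ratio of 1.37. SWI/SNF subunit genes were lower at 12 of 22 and higher at 2 (percentile 12.01), with a median difference of -1249 bases that turned to 1078 bases (percentile 73.8) at a −log10 q of at least 5. ARID1B, the paralog of ARID1A, had 77712 control and 59170 knockout bases and SMARCC1 had 26621 and 13342, whereas ARID2 had 6929 and 11545 and SMARCB1 had 5554 and 7840. Luminal breast genes were lower at 8 of 18 and higher at 2 (percentile 7.05), the 2 being MLPH with 6752 and 12770 bases and the estrogen receptor gene ESR1 with 27383 and 36816, while CA12 had 20687 and 16862.

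Mesenchymal genes were higher at 11 of 27 and lower at 6 (percentile 96.2), with COL5A1 at 12027 control and 23829 knockout bases and LOXL2 at 52923 and 37798. Matrix metalloproteinase and invasion genes were higher at 6 of 22 and lower at 5 (percentile 96.7), with ADAM12 at 29678 and 40177 bases and ADAM9 at 46318 and 33243. Epithelial genes were higher at 10 of 25 and lower at 7 (percentile 85.8), and CDH1, which encodes E-cadherin, had 16991 and 23935 bases, whereas the keratin gene KRT8 had 26176 and 22287. Basal breast genes were higher at 4 of 17 and lower at 3 (percentile 88.3). KRT6A, also a keratin gene, had 3897 control and 379 knockout bases, and MYLK had 48564 and 65042. Interferon response genes were higher at 12 of 27 and lower at 6 (percentile 90.2), with IFI44L at 6200 and 16772 bases and IFI27 at 5270 and 1616. Genes of inflammatory cytokines and NF-kB were higher at 8 of 25 and lower at 9 (percentile 80.1). CCL2 had 0 control and 6198 knockout bases, and NFKB1 had 33279 and 21857.

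**Figure D2:**
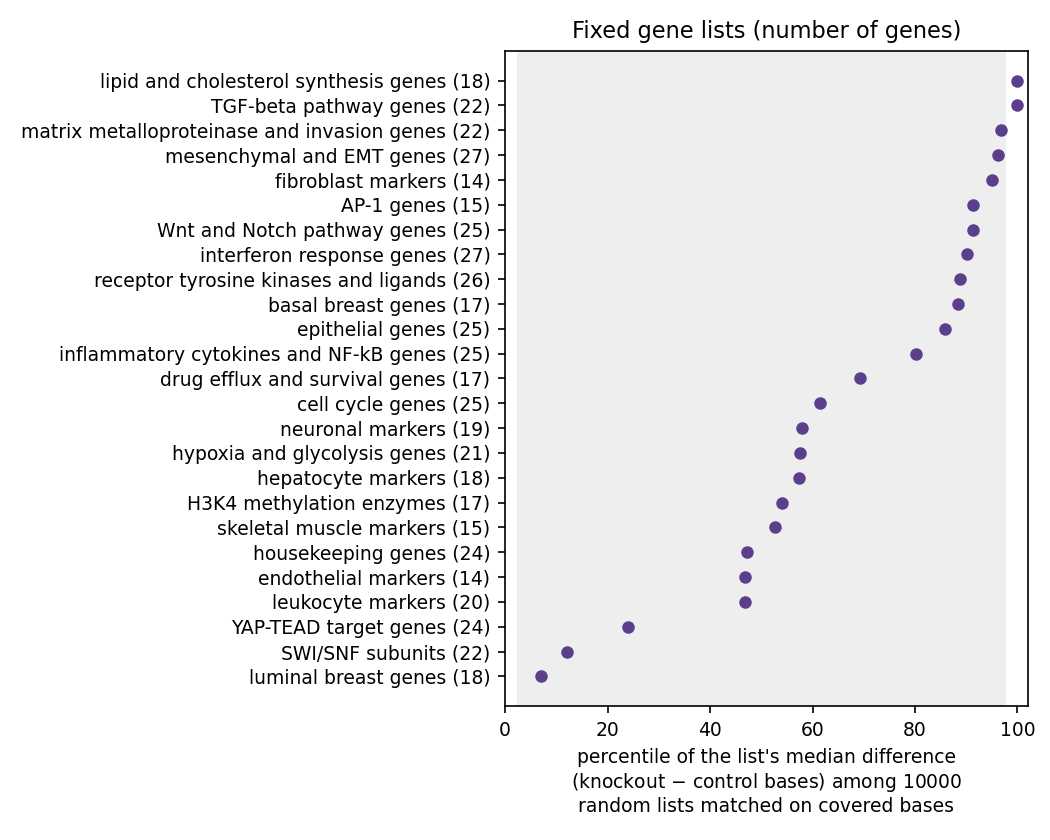
Each point is 1 fixed gene list (number of genes in brackets), placed on the horizontal axis at the percentile of its median difference in covered bases, knockout minus control, among 10000 matched random lists. The grey band is the central 95%, and the lists of lipid and cholesterol synthesis (99.95) and the TGF-beta pathway (99.89) lie above it.

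Few strong peaks of either list lacked overlap in the full opposite list, and peaks without overlap were mainly weak ones. Of the 82994 control peaks, 23368 (28.2%, 95% exact interval 27.9 to 28.5) overlapped no knockout peak, and of the 73600 knockout peaks 15685 (21.3%, 21.0 to 21.6) overlapped no control peak. When a list was shifted at random along its chromosomes, 88.7% of control peaks and 87.5% of knockout peaks were left without overlap on average. In the quartile of lowest −log10 q, 61.6% of control peaks (60.9 to 62.3) and 50.7% of knockout peaks (49.95 to 51.4) had no overlap. In the highest quartile 2.67% (2.46 to 2.90) and 1.58% (1.41 to 1.77) had none. Strong peaks were also wider, which makes overlap easier. Median widths in the lowest and highest quartiles were 729 and 2833 bases in the control list and 816 and 3192.5 in the knockout list. The opposite list was used with its weak peaks, so this pattern does not separate the genotypes. The control list covered 183.2 Mb and the knockout list 176.3 Mb, and 54.8% of the bases covered by either were covered by both. Which list held more peaks depended on the threshold. The knockout list held 0.887 times as many as the control list in full, and 27571 against 23884, or 1.15 times as many, at a −log10 q of at least 5. At a fold of at least 4 it held 0.878 times as many. Because fragment lengths appear to differ, neither cutoff is known to be equally strict in both lists. With both lists restricted by −log10 q, 24.9% of control and 35.1% of knockout peaks had no overlap. With both restricted by fold, 47.2% and 39.99% had none. In these settings, as in full, the list with more peaks had the larger percent. The order of the percentages thus adds little to the peak numbers.

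**Figure D3:**
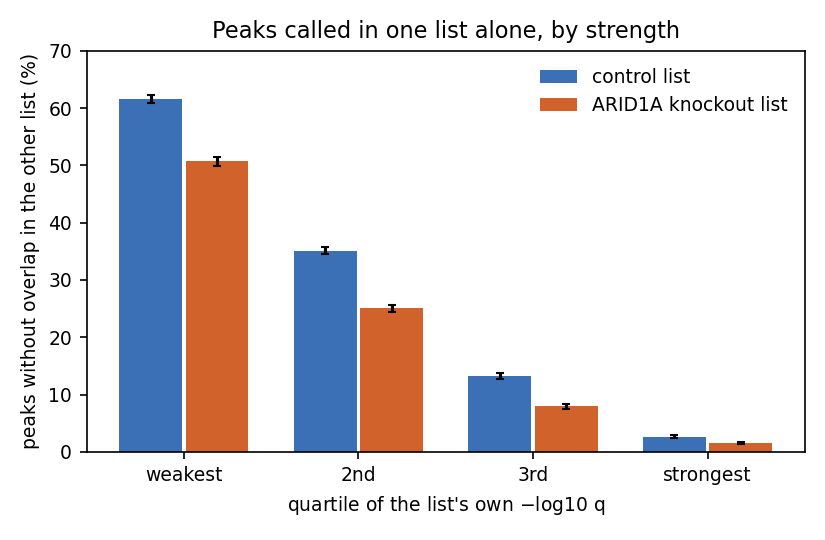
Bars give the percent of peaks of the control list (blue) and the ARID1A knockout list (orange) without overlap in the full opposite list, for quartiles of each list's own −log10 q, and error bars are 95% exact binomial intervals for counting error. The percent falls from 61.6 to 2.67 in the control list and from 50.7 to 1.58 in the knockout list.

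Peaks found in 1 list lay farther from genes than shared peaks. In the knockout list, 30.5% of single-list peaks (29.7 to 31.2) had their midpoint more than 50000 bases from any protein-coding gene, against 15.8% of shared peaks (15.5 to 16.1). In the control list the values were 24.6% (24.0 to 25.1) and 15.7% (15.4 to 16.0). Midpoints within 1000 bases of a gene end made up 4.33% of single-list and 9.12% of shared peaks in the knockout list, and 5.34% and 8.15% in the control list. Shared peaks were stronger, so single-list peaks of the stronger 50% of each list were set against shared peaks of its weaker 50%. This contrast reverses the order of strength and does not match it. The share far from genes then was 29.1% against 17.8% in the knockout list, and the share at gene ends 5.55% against 9.25%. In the control list it was 19.7% (18.4 to 21.1) against 19.5% (19.0 to 20.1) far from genes and 8.60% (7.67 to 9.61) against 8.71% (8.33 to 9.09) at gene ends, differences within the intervals. Far from genes, the contrast itself lowered the share of single-list control peaks (24.6% to 19.7%) and raised that of shared ones (15.7% to 19.5%). The control agreement therefore does not show that strength accounts for the excess. Peaks of like strength were not compared.

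In the full lists, chromosome 13 was the only one of the 23 chromosomes with more peaks in the knockout list, 2506 against 2382 in the control list, a ratio of 1.05 (0.994 to 1.11). Of its knockout peaks 32.1% (30.3 to 34.0) had no control overlap, against 21.3% in the whole list. Chromosome X had the lowest ratio, with 1458 knockout and 1972 control peaks (0.739, 0.690 to 0.792), and 38.9% of its control peaks (36.8 to 41.1) had no knockout overlap. Among peaks with a −log10 q of at least 5 the ratio on chromosome 13 was 1.83, and the highest of the other chromosomes was 1.48, on chromosome 4, while the lowest was then chromosome 22 (0.841) and no longer chromosome X. The median over chromosomes was 1.13 at that cutoff, so chromosome 13 was then not alone in having more knockout peaks.

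**Figure D4:**
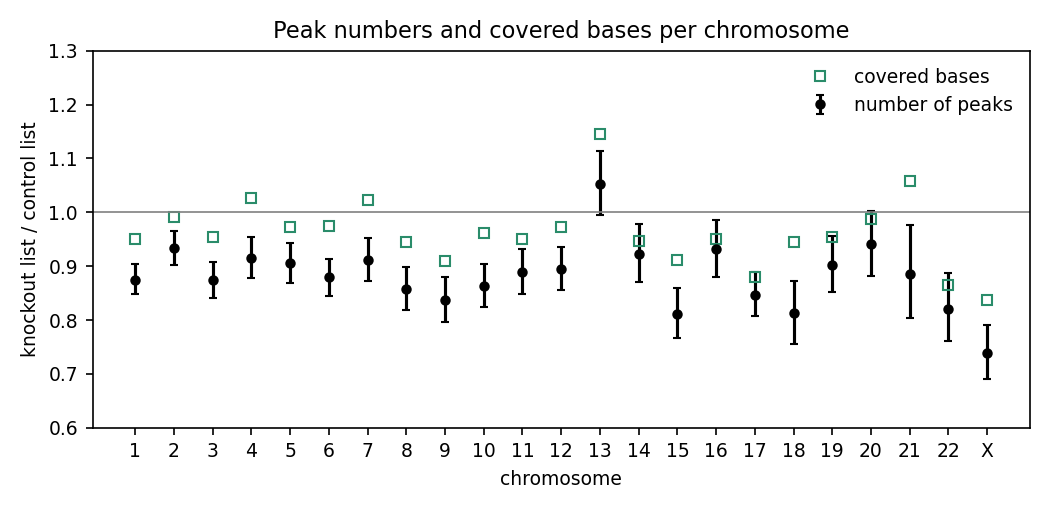
For each chromosome (horizontal axis), filled circles give the number of knockout peaks over the number of control peaks, with 95% exact intervals for counting error, and open squares give the same ratio for covered bases. Chromosome 13 has the highest ratio of peaks (1.05) and chromosome X the lowest (0.739).

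Some regions of 5 Mb differed much more than whole chromosomes. Between 25 and 30 Mb of chromosome 14, 13 control peaks covered 13717 bases and 66 knockout peaks covered 121560 bases, the highest ratio of covered bases (8.86) among 571 regions with at least 40 peaks in the 2 lists together. That region holds PRKD1, a protein kinase gene, with 0 control and 2447 knockout bases. NOVA1, a neuronal RNA-binding protein gene there, had no peak in either list. Of the 66 knockout peaks 58 lay beyond 27 Mb. Between 70 and 75 Mb of chromosome 18 coverage was 69885 bases in the control list and 164585 in the knockout list, with NETO1 at 0 and 20666. The control and knockout backgrounds there (2.41 and 2.64) were near the lowest of their lists, so the implied background ratio says nothing. Between 125 and 130 Mb of chromosome 12, TMEM132D had 26465 control and 67154 knockout bases. The lowest ratio, 0.274, lay between 25 and 30 Mb of chromosome X, where IL1RAPL1, a synaptic adhesion gene, had 36824 control and 15980 knockout bases. The implied background ratio of that region was 0.862. A lower one cannot be ruled out, because the knockout background (2.66) was near the lowest of its list. Between 95 and 100 Mb of chromosome 6, FUT9, a fucosyltransferase gene, had 5358 and 0 bases. Between 50 and 55 Mb of chromosome 10, PRKG1, a cGMP-dependent kinase gene, had 46298 and 12586. The genes of these regions were chosen after their values were seen. Other regions ranked between these and are not described, such as 20 to 25 Mb of chromosome 19. Its ratio of covered bases was 3.76 and its implied background ratio 1.48.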

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

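The ratios of peak numbers at a −log10 q of at least 5 and at a fold of at least 4 were alternatives planned before the data were examined, whereas their use to weigh an explanation, the other tests of this part and the bounds used to judge them were chosen only after the results were seen. The input background implied by the lists was given above only beside single genes. It is derived from the pileup and the fold, so the filter by fold depends on it. This background was compared between genotypes by chromosome, and chromosomes more than 0.25 from the median on the log2 scale were singled out. Chromosome 13 stood at 1.399 times the median ratio of knockout to control and chromosome 3 at 0.832 times. On chromosome 3 the knockout to control ratio was 0.874 (0.841 to 0.908) for peak numbers and 0.954 for covered bases. Those of the whole lists were 0.887 and 0.962.

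Chromosome 13 was also the only chromosome with more peaks in the knockout list at the authors' threshold. The different merging of the 2 lists does not account for this, since the ratio of its peak numbers was 1.13 with the same merging and shortest peak in both, above the highest of the other chromosomes (1.02). More copies of chromosome 13 in the knockout cells are a candidate explanation that stays open: its implied background ratio of 1.399 lay above the highest of the other chromosomes, 1.11, and its regions of highest background, 1.52 at 40 to 45 Mb and 1.56 at 45 to 50 Mb, had ratios of 1.02 and 0.946 for peak numbers and 1.18 and 1.16 for covered bases. In 53 regions of other chromosomes with an implied background ratio of at least 1.2, the ratio of peak numbers was 0.962 (0.933 to 0.992), above the 0.873 (0.864 to 0.883) of the remaining regions and short of the 1.05 of chromosome 13. The estimate comes from peaks alone, and whether a difference came with the loss of ARID1A or was carried by the cells grown out as knockout was not tested.

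The knockout list held fewer peaks than the control list. Whether weak peaks near the authors' threshold account for that stays open, because the ratio turned to 1.15 among peaks with a −log10 q of at least 5 but was 0.878 among peaks with a fold of at least 4. The different fragment lengths cannot be told apart from a loss of peaks, since the same merging and shortest peak moved the ratio only to 0.951, and the effect of fragment length on the q values was not redone. Lower depth of the knockout samples also stays open: the lowest implied background per base of shortest peak, an indirect measure of depth, was 0.935 times that of the control list. A loss of H3K4me1 sites through loss of ARID1A stays open and untested.

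Clusters of knockout peaks at TCF4 and between 25 and 30 Mb of chromosome 14 are a further pattern. A local gain of copies stays open. The implied background ratios were 0.919 at TCF4 and 1.08 in the chromosome 14 region. At TCF4 the knockout background (2.73) lay more than 3% above the floor of its list. The control background (2.44 and 2.45), however, was near the floor of its own list (2.40), so the test could not rule a gain out. Weak peaks near the threshold stay open at both: a first test found 3272 knockout and 0 control bases at TCF4 at a −log10 q of at least 5, and 44995 and 3481 in the chromosome 14 region, which decided neither. A second test, added because of that, found that 50% (1 of 2) of such knockout peaks at TCF4 and 60% (6 of 10, 26.2 to 87.8%) of those on chromosome 14 had no overlap in the full control list, against 2.77% over all chromosomes. The chromosome 14 value alone argues against weak peaks, but it comes from a test picked after the first had decided nothing and from a region picked for its difference, so the question is left open, as is an effect of ARID1A loss, which was not tested.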

How the results depend on the processing

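The alternatives with the same merging, with 10000 or 50000 bases beside genes, and with random lists matched on implied background were chosen after the data were seen. So was the location of stronger single-list against weaker shared peaks. No paired analysis was possible because each genotype had 1 list, which also ruled out leaving out a replicate. The planned merging of peaks within 1000 bases moved nothing, since no gap was that short. The planned windows around transcription start sites and the motif counts were not run. The cause of the shifts given here was not tested.

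At a −log10 q of at least 5 in both lists, the knockout to control ratio reversed to 1.15 for peaks and 1.14 for covered bases, 24.9% of control and 35.1% of knockout peaks had no overlap, and 50.5% of bases were in both lists. At a fold of at least 4 these values were 0.878, 0.894, 47.2%, 39.99% and 41.1%. With the same merging and shortest peak they were 0.951, 0.946, 26.6%, 22.2% and 55.3%. With lists of equal length 22.9% of control and 24.7% of knockout peaks had no overlap, so their order turned, and 55.4% of bases were in both. Asking for overlap of 50% of a peak gave 38.3% and 32.4% without overlap, and counting peaks within 1000 bases as shared gave 27.2% and 20.4%. Peaks with a −log10 q of at least 5 had no overlap in the full other list in 3.23% of control and 2.77% of knockout cases. The strongest quartile by fold had 3.61% and 2.78% without overlap. With stronger single-list peaks set against weaker shared peaks, the excess far from genes was 0.169 percentage points in the control list and 11.3 in the knockout list. That contrast does not match strength, so these are not excesses at like strength. With 2500 bases instead of 1000, gene ends held 10.2% of single-list and 21.3% of shared control peaks and 8.32% and 21.7% of knockout peaks. With any overlap of the peak they held 7.35% and 18.4%, and 6.32% and 18.9%. With stronger single-list set against weaker shared peaks, the control shares at gene ends were 15.5% and 20.3% with 2500 bases. They were 12.3% and 15.3% with any overlap, so their agreement at 1000 bases did not hold there. The chromosome 13 ratio was 1.83 at a −log10 q of at least 5 and 1.13 with the same merging.

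The TGF-beta list moved to percentile 91.3 at a −log10 q of at least 5. It stayed above the central 95% under the other alternatives run on gene lists, as the lipid list did under all of them. A fold of at least 4 was not run on gene lists or named genes. With 50000 bases beside genes, mesenchymal (99.8), basal (98.5) and YAP-TEAD genes (2.42) also fell outside it, and with the same merging mesenchymal genes did (98.2). The sign of the list median turned at a −log10 q of at least 5 for 6 of 25 lists, none of them outside the central 95% in either setting. They were SWI/SNF (-1249 to 1078 bases), YAP-TEAD (-1286 to 172), H3K4 methylation enzymes (-298 to 743), hypoxia (-494 to 481), cell cycle (-238 to 282) and housekeeping genes (-432.5 to 118). All 6 turned upward, as covered bases over the whole lists did (knockout over control, 0.962 to 1.14), so the turn is not particular to them. The sign turned for 2 lists with 10000 bases beside genes (AP-1, Wnt and Notch), for 5 with 50000 (these and the cell cycle, invasion and receptor kinase lists) and for receptor kinase genes with the same merging. Of 100 values for 20 named genes, 88 kept the direction and stayed within 1.5 times of the reported difference (or, on the log2 scale, kept the direction), 11 kept the direction but differed by more than that (at a −log10 q of at least 5, TCF4 and the 8 genes named for this above, and ARID1A, at -12512 there and -14489 with 50000 bases on either side, against -5482), and 1 reversed, KYNU to -90 bases at a −log10 q of at least 5. Unknown depth limits what can be said of weak peaks.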

Other observations

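No test in this part bears on an explanation, and the genes named in its gene lists are those the fixed rule took. Receptor tyrosine kinase and ligand genes were higher in the knockout list at 12 of 26 and lower at 6 (percentile 88.7). The ligand gene NRG1 had 94036 control and 134190 knockout bases and the receptor gene IGF1R had 105102 and 70854. Wnt and Notch pathway genes were higher at 8 of 25 and lower at 8 (percentile 91.3), with TCF7L2, a nuclear effector of Wnt signalling, at 59635 and 75971 bases and the receptor gene NOTCH2 at 10204 and 5502. AP-1 genes were higher at 4 of 15 and lower at 4 (percentile 91.3), with MAF at 4136 and 10389 bases and ATF3 at 19190 and 12794. Hypoxia and glycolysis genes were higher at 6 of 21 and lower at 8 (percentile 57.6), cell cycle genes at 6 and 10 of 25 (61.4), and genes of drug efflux and survival at 3 and 6 of 17 (69.2). CDK6 had 108204 and 118371 bases and CDK1 had 15183 and 11779. ABCC1 and ABCC2, drug efflux pump genes, had 47982 and 8971 control bases and 36575 and 13379 knockout bases. The medians of the hypoxia and cell cycle lists turned from -494 and -238 bases to 481 and 282 at a −log10 q of at least 5. Genes of H3K4 methylation enzymes were higher at 5 of 17 and lower at 7 (percentile 54.1), with a median of -298 bases that turned to 743 at that threshold, and KMT2C, which encodes an H3K4 methyltransferase that acts at enhancers, had 41926 and 29361 bases, whereas the demethylase gene KDM5A had 5223 and 7502. The regions of NOTCH2, ATF3 and CDK6 had implied background ratios of 0.658, 1.37 and 1.47.

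Marker genes of cell types other than breast epithelium gave no list outside the central 95%. Fibroblast markers were higher at 4 of 14 and lower at 3 (percentile 94.985), with FBLN2 at 9419 control and 16283 knockout bases and MFAP5 at 1780 and 0. Endothelial markers were higher at 4 of 14 and lower at 4 (percentile 46.8), with PECAM1 at 20018 and 41725 bases, whereas VWF had 21042 and 14394 and TEK had 19657 and 13196. Leukocyte markers were higher at 3 of 20 and lower at 6 (percentile 46.8), with PTPRC at 9452 and 21892 bases and ITGAX at 5627 and 0. Neuronal markers were higher at 5 and lower at 5 of 19 (percentile 57.9), hepatocyte markers at 2 and 3 of 18 (57.4), skeletal muscle markers at 1 and 3 of 15 (52.7) and housekeeping genes at 7 and 9 of 24 (47.3, with a median of -432.5 bases that turned to 118 at a −log10 q of at least 5). Median and mean differences had opposite signs for AP-1 genes (501 and -354 bases), invasion genes (365.5 and -135), cell cycle genes (-238 and 116), leukocyte markers (-30.5 and 42.3) and endothelial markers (-253.5 and 73.5). The regions of FBLN2, TEK and PTPRC had implied background ratios of 0.738, 0.772 and 1.31, which at TEK and PTPRC ran the same way as the difference in covered bases.

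The implied background ratio reached 1.89 and 1.83 in the regions of 50 to 55 and 55 to 60 Mb of chromosome 6, with 109 control and 112 knockout peaks in the first and 85 and 88 in the second. It was 1.62 between 65 and 70 Mb of chromosome 7, where a higher ratio cannot be ruled out because the control background was near its floor. In that region 36 control and 85 knockout peaks were called and TPST1, chosen after its values were seen, had 4786 and 18464 covered bases. Between 35 and 40 Mb of chromosome 22 it was 0.615, where 362 control and 272 knockout peaks were called.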
